A study of Rattus norvegicus with 23 samples.

How the data were processed

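The study measured left ventricular gene expression in rats with Affymetrix Rat Genome U34 oligonucleotide arrays. Per the labels, the arrays came from spontaneously hypertensive rats (SHR), an inbred strain with inherited high blood pressure, and from age-matched Wistar-Kyoto rats (WKY), the related strain used as its normotensive control. Animals were 12, 16 or 20 months old. There were 23 arrays, with 4 arrays in each of 5 groups and 3 arrays in the WKY group of 20 months. The labels call them samples and do not say whether each came from a separate animal, so the p-values measure the spread between these samples, which may in part be technical.

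The values analysed were the probe set intensities deposited by the authors, on a linear scale, with 1 value per probe set and array. The program that summarised the probes, its version and its scaling are not given in the sources used here. The deposited intensities held no value below 0, and the 2% trimmed mean lay between 50.08 and 50.11 on every array while the medians ran from 9.4 to 13.3, which shows that each array had been scaled to a common trimmed mean before deposit. Detection calls were not used here. The number of arrays limits the precision.

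The authors also deposited the instrument's text record of each array, whose entries (unit other) were used only to group arrays by hybridization day, chip lot, hybridization cocktail, fluidics station and module. All 12 SHR arrays were hybridized with cocktail 1 on days 1 to 4 and all 11 WKY arrays with cocktail 2 on days 5 and 6. The chip lots also differed between the strains, and 2 SHR arrays had no lot recorded. Day 1 held 2 SHR arrays of 12 months, day 2 held 2 SHR arrays of 12 months and 2 of 16 months, day 3 held the other 2 SHR arrays of 16 months, and day 4 held all 4 SHR arrays of 20 months. Day 5 held all WKY arrays of 12 months and of 16 months, on different stations, and day 6 held the WKY arrays of 20 months. No day, recorded lot or cocktail held both strains, so strain and run cannot be told apart in any strain comparison.

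The table held 8799 probe sets, of which 59 were controls. The platform annotation, dated 2016, gave 1 gene symbol for 7006 probe sets, several for 308 and none for 1426. Of the probe sets with 1 symbol, 6985 were matched by Entrez identifier to the GRCr8 gene table, and 0 symbols changed. Genes were named only from probe sets with 1 symbol. The annotation names no genome build for the array, so no coordinates are given.

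Intensities were used as deposited, 32 was added, and log2 values were taken. Fold changes are therefore on the log2(intensity + 32) scale, which understates the change of dim genes. Probe sets other than controls were tested if they lay above the 30th percentile of an array on at least 3 arrays, which left 7280 probe sets. Of these, 5920 had 1 symbol. A linear model with the 6 groups was fitted over all 23 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend). The 12 comparisons were the strain difference at each age and averaged over the ages, the differences between ages within each strain, and 2 strain by age interactions. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the probe sets of a comparison, and an adjusted p below 0.05 is called a change. Errors of log2 changes are standard errors from this model, and levels are mean intensities ± SD.

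For gene lists, each of 4172 genes was represented by its probe set of highest mean log2 value. Lists of 764 genes in all were fixed before the data were examined, of which 538 were measured, and ribosomal protein genes were added by symbol, a pattern that also takes S6 kinase genes. The 27 lists had at least 5 measured members each. They were tested with camera in limma at the preset correlation of 0.01, again with the correlation estimated, and with fry, with Benjamini-Hochberg adjustment over the 27 lists. A list is called at an adjusted p below 0.05 with the preset correlation, and the p with an estimated correlation is printed beside it.

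The genes named were chosen by a rule written before the data were examined. For the strain difference at each age, SHR at 20 against 16 and 12 months, WKY at 20 against 12 months and both interactions, the rule took the 8 genes with the largest rise and the 8 with the largest fall among those with an adjusted p below 0.05 and, for comparisons of 2 groups, no overlap between the groups' arrays. For the other comparisons it took 3 of each. Where none passed, it took the 3 genes of smallest p. It added up to 3 members of each list with the smallest p, and Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Fn1, Timp1, Thbs4, Postn, Lox, Spp1 and Cd36. The text names only a part of the genes that the rule took, and that part was picked after their values were seen. Genes behind counts of 5 or fewer that the rule did not take were also named after their values were seen, as were the genes Calr, Ndufab1 and Lamb2.

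The functions were tested on simulated arrays drawn from the real means and residual spreads, with independent noise between genes and 200 changed probe sets. For SHR at 20 against 12 months, 79.1% of changes of 0.5 log2, 92.5% of changes of 1 log2 and 89.4% of changes of 2 log2 were found, with 8 false calls among 182 over 7134 probe sets. For the interaction from 12 to 20 months the shares were 46.3%, 76.1% and 84.8%, with 6 false calls among 144 over 7120 probe sets. For the strain difference at 12 months, 89.6% of changes of 0.5 log2 were found over 7126 probe sets, with 16 false calls among 195. For WKY at 20 against 12 months, 71.6% of changes of 0.5 log2 were found over 7121 probe sets. A matrix list shifted by 0.3 log2 in a simulated SHR 20 months group was called over 4086 genes with either correlation, and of 26 unshifted lists 1 was called with the preset correlation and 0 with an estimated one.

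Alternatives covered the pseudocount, the filter, the normalization (quantile, cyclic loess, median centring), the arrays in the fit, the variance model, array weights, the replicate number as a block, the hybridization day as a block, and leaving out each array in turn. The chip lot and the station could not be fitted as blocks, because each lot held 1 strain only and the second station held 1 group only. Figures were drawn with matplotlib 3.10.9.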

Results

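Left ventricular RNA from SHR and WKY rats of 12, 16 and 20 months was profiled on 23 arrays. The design asks how the ventricle of the hypertensive strain differs from that of its control strain at each age, how each strain changes with age, and whether the change with age differs between the strains. The labels list heart failure among their keywords. The first principal component of the 7280 tested probe sets held 42.6% of the variance and separated the strains, whose arrays were also hybridized on different days with different chip lots and cocktails. Spiked bacterial control transcripts, which are added in fixed amounts and are not rat RNA, were brighter on the SHR arrays by a median of 0.70 on the log2 scale over 9 probe sets. The ratio of the 3' to the 5' probe set of hexokinase ran from 2.3 to 3.53 on SHR arrays and from 3.2 to 5.82 on WKY arrays. The same ratio of beta-actin went from 1.31 ± 0.10 at 12 months to 1.18 ± 0.14 at 20 months in SHR (SD, n = 4 each) and from 1.41 ± 0.19 (SD, n = 4) to 1.80 ± 0.23 (SD, n = 3) in WKY.

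**Figure D1:**
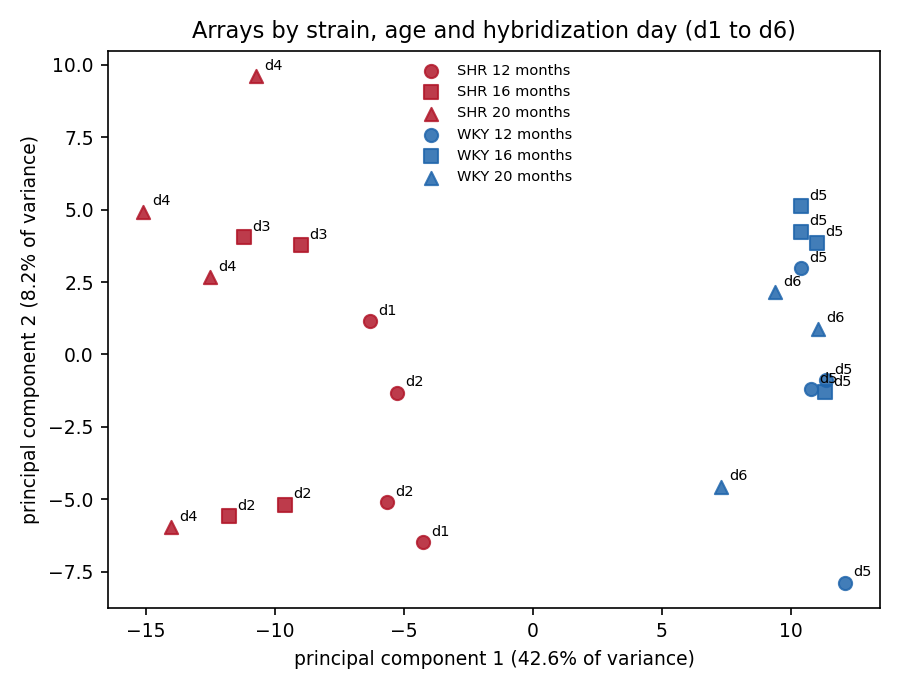
Each point is 1 array, placed by its scores on principal component 1 (42.6% of variance) and principal component 2 (8.2% of variance) of the log2 values, without unit. Red points are SHR and blue points WKY, shapes give the age, and d1 to d6 give the hybridization day. All SHR arrays lie at scores of -4.25 or below on component 1 and all WKY arrays at 7.3 or above, and no day holds both strains.

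The clearest change with age was in the SHR ventricle between 12 and 20 months, where genes of the extracellular matrix rose and genes of fatty acid oxidation and oxidative phosphorylation fell. Thbs4, a matricellular thrombospondin, rose from an intensity of 39.5 ± 14.3 (SD, n = 4) to 214 ± 25 (SD, n = 4), a log2 change of 1.80 ± 0.16 (SE; limma, Benjamini-Hochberg adjusted p = 6.49e-08). The fibrillar collagen gene Col3a1 rose from 168 ± 37 to 407 ± 44 (SD, n = 4 each) and Col1a2 from 88.5 ± 19.2 to 234 ± 40 (SD, n = 4 each). Ech1, an enzyme of fatty acid oxidation, fell from 661 ± 18 to 372 ± 33 (SD, n = 4 each), a log2 change of -0.78 ± 0.12 (limma adjusted p = 0.000176).

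Of the 50 measured genes of the matrix and fibrosis list, 23 rose and 0 fell between 12 and 20 months in SHR, and 27 rose when adjusted over the list alone. The list had a median log2 change of 0.28 (camera adjusted p = 5.25e-22, adjusted p = 0.00505 with an estimated correlation). Besides Thbs4, Col3a1 and Col1a2, the risers included the crosslinking enzyme gene Loxl1 at 1.05 ± 0.15 log2, Postn (periostin) at 1.03 ± 0.11, fibronectin (Fn1) at 1.01 ± 0.11, Col1a1 at 0.99 ± 0.22 and the protease inhibitor gene Timp1 at 0.80 ± 0.11. Ltbp2, a gene of the matrix list, rose by 0.72 ± 0.06 log2 from an intensity of only 1.53 ± 0.51 to 23.3 ± 2.1 (SD, n = 4 each). Spp1 (osteopontin) rose from 12.2 ± 2.1 to 32 ± 4.13 (SD, n = 4 each). Lox passed narrowly at 0.30 ± 0.09 log2 (limma adjusted p = 0.043), at intensities of 10.4 ± 2.33 and 20.2 ± 5.6 (SD, n = 4 each), and 3 other Lox probe sets did not pass. The Fn1 call rested on the brightest of its probe sets, and 2 dim Fn1 probe sets and a second Ltbp2 probe set did not pass.

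Markers of other cells moved as well. Of 11 fibroblast markers 5 (Col1a1, Col1a2, Col3a1, Vim and Thy1) rose and 0 fell (median 0.25, adjusted p = 0.0141 with an estimated correlation), a list that shares collagen genes with the matrix list, and Thy1 rose from 16.4 ± 5.8 to 40.3 ± 5.1 (SD, n = 4 each). Of 11 macrophage and monocyte markers 3 rose and 0 fell (median 0.15, adjusted p = 0.0191 with an estimated correlation), namely Lgals3 (galectin-3) at 0.56 ± 0.11 log2, the complement gene C1qb at 0.54 ± 0.14 and the lysozyme gene Lyz2 at 0.87 ± 0.23. Of 44 genes of inflammation, complement and antigen presentation 6 rose and 0 fell (median 0.10, adjusted p = 0.008 with an estimated correlation), with C1s at 0.69 ± 0.11, Serping1 at 0.66 ± 0.12 and Icam1 at 0.49 ± 0.10. The heme oxygenase gene Hmox1 rose by 0.57 ± 0.10 log2. Of the 9 endothelial and the 9 smooth muscle and pericyte markers 0 were called, with medians of 0.09 and 0.15.

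Of 39 genes of fatty acid uptake and oxidation, 13 fell and 0 rose, and 20 fell when adjusted over the list alone (median -0.28, camera adjusted p = 3.84e-17, adjusted p = 0.00224 with an estimated correlation). Acat1, a mitochondrial thiolase gene, fell from 506 ± 18 to 310 ± 31 and Acaa2 from 1950 ± 119 to 1266 ± 110 (SD, n = 4 each). Of 42 genes of oxidative phosphorylation and the citrate cycle, 12 fell and 0 rose, and 25 fell when adjusted over the list alone (median -0.34, adjusted p = 0.00505 with an estimated correlation). The complex I genes Ndufb5 and Ndufa5 changed by -0.57 ± 0.12 and -0.54 ± 0.11 log2. Bckdha, of branched-chain amino acid breakdown, changed by -0.66 ± 0.13, the transaminase gene Got1 by -0.52 ± 0.10 and Rpl3l, a ribosomal protein gene of striated muscle, by -0.70 ± 0.13. Dhrs7c, Rxrg, Fmc1 and Vtn also fell, by log2 changes of -0.70, -0.67, -0.68 and -0.67. The early response gene Nr4a1 had the largest fall among the called genes without overlap, at -1.33 ± 0.28 log2. Another probe set each of C1qb and Fmc1 did not pass, and of 2 other probe sets each of Acat1 and Rxrg 1 passed in the same direction and 1 did not.

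Contractile and calcium cycling genes gave no list call. The sarcomere list had a median of -0.01 and the calcium handling list a median of 0.04, and neither was called. Acta1, Myh6, Myh7 and Atp2a2 did not pass in SHR between these ages, with log2 changes of 0.18 ± 0.11, -0.20 ± 0.13, -0.21 ± 0.14 and -0.13 ± 0.14. The natriuretic peptide gene Nppa rose by 0.65 ± 0.18 log2 (limma adjusted p = 0.0314), while 3 other Nppa probe sets did not pass and Nppb did not pass at 0.37 ± 0.14. The wall stress list was called at a median of 0.16 (adjusted p = 0.0401 with an estimated correlation), with 3 of 14 genes risen (Nppa, Ckb and Myl4). The atrial marker list lost its call with an estimated correlation (adjusted p = 0.119), and of 11 nerve and Schwann cell markers 2 rose (Pmp22 and Nefm; median 0.09, adjusted p = 0.0356 with an estimated correlation). The remaining 18 lists were not called, with medians between -0.09 and 0.15.

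In all, limma called 337 probe sets in this comparison, 191 higher and 146 lower at 20 months, and 1105 passed an unadjusted p of 0.05, where 364 were expected by chance. The share of higher calls was 56.7% and became 39.4% when arrays were centred on their medians. All 4 SHR arrays of 20 months were hybridized on a day of their own, and with the day as a random block 214 probe sets were called. Leaving out SHR 12 months replicate 2, 3 or 4 left 199, 208 or 212 calls and leaving out SHR 20 months replicate 3 left 160. Fmc1, Spp1, Lox, Icam1, C1qb, Lyz2 and Nppa lost their calls under at least 1 alternative.

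**Figure D2:**
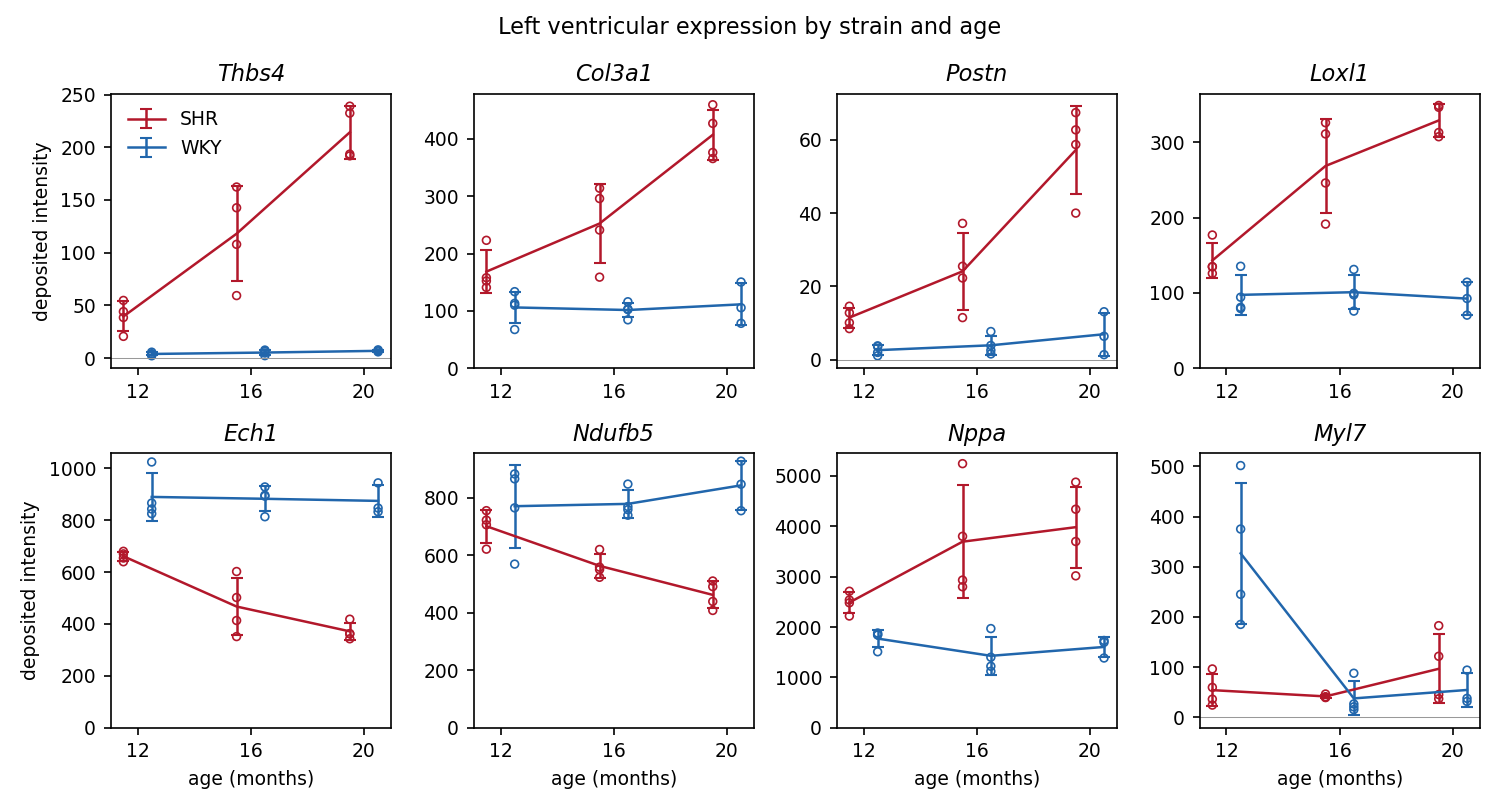
Deposited intensity (vertical axis, linear) of 8 genes against age in months, with SHR in red and WKY in blue, drawn slightly apart at each age. Open circles are arrays and lines join group means with bars of 1 SD (n = 4, and n = 3 for WKY at 20 months). Thbs4 reaches 214 in SHR at 20 months and stays below 8 on every WKY array, Ech1 falls to 372 in SHR, and Myl7 is highest on the 4 WKY arrays of 12 months.

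In the earlier step in SHR, from 12 to 16 months, fewer genes were called. Thbs4 rose from 39.5 ± 14.3 to 118 ± 45 (SD, n = 4 each), a log2 change of 1.04 ± 0.16 (limma adjusted p = 0.00459). Bgn (biglycan) rose by 0.81 ± 0.15, Tsc22d1 by 0.81 ± 0.17, Loxl1 by 0.76 ± 0.15 and Fn1 by 0.52 ± 0.11 log2. Acat1, the acyl-CoA thioesterase gene Acot2 and the mitochondrial import gene Grpel1 changed by -0.62 ± 0.11, -0.65 ± 0.15 and -0.40 ± 0.09 log2. Of the matrix list 5 genes (Thbs4, Bgn, Loxl1, Fn1 and Ltbp2) rose and 0 fell (median 0.14, adjusted p = 0.13 with an estimated correlation). Of the fatty acid list 2 fell and 0 rose (median -0.10, adjusted p = 0.0129 with an estimated correlation). Of the oxidative phosphorylation list 0 were called (median -0.18, adjusted p = 0.0755 with an estimated correlation). The wall stress, macrophage and oxidative stress lists also lost their calls (adjusted p = 0.151, 0.13 and 0.0596 with an estimated correlation). Second probe sets of Loxl1 and Acot2, and 2 other probe sets each of Fn1 and Acat1, did not pass. Day 2 held 2 arrays of each age, and within that day alone the medians of the matrix, fatty acid and oxidative phosphorylation lists were 0.15, -0.15 and -0.16.

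Between these ages limma called 27 probe sets, 20 higher and 7 lower, and 925 passed an unadjusted p of 0.05. The share of higher calls, 74.1%, was 54.3%, 63% and 41.7% after quantile, cyclic loess and median scaling. With the day as a fixed block 42 were called and within day 2 alone 0. Without SHR 12 months replicate 2 there were 4, without SHR 16 months replicate 1 there were 69. Each of the 8 genes named here lost its call under at least 1 alternative.

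From 16 to 20 months in SHR, 6 probe sets rose and 0 fell. Postn rose from 24.1 ± 10.6 to 57.2 ± 12 (SD, n = 4 each), a log2 change of 0.68 ± 0.11 (limma adjusted p = 0.00823). Ltbp2 rose by 0.44 ± 0.06, the collagen-degrading protease gene Ctsk by 0.44 ± 0.07, Spp1 by 0.44 ± 0.09, the atrial myosin light chain gene Myl4 by 0.54 ± 0.10 and the hemoglobin gene Hbb-b1 by 0.74 ± 0.14 log2. Thbs4 went from 118 ± 45 to 214 ± 25 (SD, n = 4 each) and did not pass (limma adjusted p = 0.0529), and neither did second probe sets of Ltbp2 and Myl4. The matrix list had a median of 0.16 with 3 genes risen, Postn, Ltbp2 and Spp1 (adjusted p = 0.0329 with an estimated correlation), and the fibroblast list a median of 0.35 with 0 genes called (adjusted p = 0.0329 with an estimated correlation). The inflammation list had a median of 0.08 with 0 genes called (adjusted p = 0.02 with an estimated correlation). The fatty acid, oxidative phosphorylation, oxidative stress and immediate early gene lists lost their calls (adjusted p = 0.181, 0.141, 0.0678 and 0.181 with an estimated correlation).

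In this comparison 630 probe sets passed an unadjusted p of 0.05. Calls numbered 3 with the day as a random block, 0 when only the 8 arrays compared were fitted, 13, 12 and 3 without SHR 16 months replicate 2, 3 or 4, and the share of higher calls, 100%, was 88.9% after quantile and 85.7% after cyclic loess normalization. Each of the 6 called genes lost its call under at least 1 alternative.

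In WKY, few genes changed with age. Myl7, the atrial regulatory myosin light chain, was at 327 ± 141 (SD, n = 4) at 12 months, at 37.6 ± 33.8 (SD, n = 4) at 16 months and at 54.4 ± 34.4 (SD, n = 3) at 20 months. It fell between 12 and 16 months by 2.39 ± 0.33 on the log2 scale (limma adjusted p = 0.00113) and between 12 and 20 months by 2.04 ± 0.36 (limma adjusted p = 0.0147). A second Myl7 probe set did not pass in either step (limma adjusted p = 0.0503 and 0.186). Oaz2, an inhibitor of polyamine synthesis, went from 1575 ± 256 (SD, n = 4) to 772 ± 134 (SD, n = 3) between 12 and 20 months, a fall that passed (limma adjusted p = 0.0147). Thbs4, Col3a1 and Postn did not pass in WKY from 12 to 20 months, with log2 changes of 0.12 ± 0.17, 0.05 ± 0.19 and 0.16 ± 0.12.

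Limma called 1 probe set between 12 and 16 months (348 at an unadjusted p of 0.05), 0 between 16 and 20 months (355) and 4, all lower, between 12 and 20 months (477), which were Myl7, Oaz2, a probe set of the complex I gene Ndufab1 and a probe set without a symbol. The brightest Ndufab1 probe set did not pass. The 3 genes of smallest p between 16 and 20 months, Cnrip1, Slc41a3 and Egr1, did not pass, with log2 changes of -0.41 ± 0.08, -0.52 ± 0.11 and -1.14 ± 0.26. The matrix list had a median of 0.03 and the oxidative phosphorylation list a median of 0.07 from 12 to 20 months, and neither was called. Between 12 and 16 months the atrial and wall stress lists, which both hold Myl7, were called downward (adjusted p = 0.0362 and 0.048 with an estimated correlation), and the ribosomal protein and immediate early gene lists lost their calls (adjusted p = 0.505 and 0.162 with an estimated correlation). Between 16 and 20 months the oxidative phosphorylation, sarcomere, heat shock and ribosomal protein lists (adjusted p = 0.535 for each with an estimated correlation) and the immediate early gene list (adjusted p = 0.15 with an estimated correlation) lost theirs. Between 12 and 20 months the wall stress and heat shock lists lost theirs (adjusted p = 0.292 and 0.696 with an estimated correlation). The calls from 12 to 20 months fell to 0 with the day as a random block, without WKY 12 months replicate 1 and without WKY 20 months replicate 2. Those from 12 to 16 months became 2 without WKY 12 months replicate 4 or WKY 16 months replicate 2.

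On these arrays matrix genes changed more from 12 to 20 months in SHR than in WKY. In both strains the 20 months arrays had a hybridization day of their own, so age and day cannot be told apart in this interaction. Splits of the arrays, given below, did not exclude chance for the count of calls. Thbs4 had an interaction of 1.69 ± 0.23 log2 toward SHR (limma adjusted p = 0.000426), Ltbp2 of 0.71 ± 0.09, Loxl1 of 1.10 ± 0.22, Col1a2 of 1.03 ± 0.23, Postn of 0.87 ± 0.17 and Fn1 of 0.78 ± 0.15. In WKY, Thbs4, Ltbp2 and Postn lay far below the added 32, which compresses any change there. Under the alternatives the Postn interaction ran from 0.43 to 1.34 log2, with a limma adjusted p of up to 0.506. A second Ltbp2 probe set (0.02 ± 0.08) and 2 other Fn1 probe sets (-0.10 ± 0.11 and 0.25 ± 0.15) did not pass. The elastin gene Eln went from 31.9 ± 18.5 to 61.8 ± 6.5 in SHR (SD, n = 4 each) and from 51.7 ± 12.3 (SD, n = 4) to 25.3 ± 14 (SD, n = 3) in WKY. Tsc22d1 and the actin capping gene Capg had interactions of 1.22 ± 0.24 and 0.89 ± 0.17, with means that went up in SHR (362 to 745 and 69.4 to 130) and down in WKY (551 to 460 and 61.4 to 47.1). Rpl3l, Ech1 and Pllp had interactions of -1.07 ± 0.20, -0.76 ± 0.17 and -0.69 ± 0.15 log2. In WKY the mean of Ech1 went from 889 to 874, while those of Rpl3l and Pllp went up, from 319 to 422 and from 47.9 to 61.2. None of these 5 genes passed in WKY alone, and a second Rpl3l probe set did not pass for the interaction (-0.39 ± 0.15).

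Of the 50 matrix genes, 8 had a called interaction, all upward, and 22 had when adjusted over the list alone (median 0.33, adjusted p = 0.0069 with an estimated correlation). The oxidative phosphorylation list had a median interaction of -0.42 and the fatty acid list of -0.27 (adjusted p = 0.0069 for both with an estimated correlation), with 0 and 1 genes called. The fibroblast, macrophage, inflammation, wall stress and atrial lists shifted upward with medians of 0.37, 0.18, 0.11, 0.17 and 0.27, and kept their calls with an estimated correlation. The largest interaction was Myl7 at 2.53 ± 0.49 log2, a gene highest on the WKY arrays of 12 months. It rests on a single probe set, since a second Myl7 probe set had an interaction of 0.93 ± 0.25 and did not pass (limma adjusted p = 0.092). Myl4, at 1.00 ± 0.15, went from 13 ± 3.7 to 30.6 ± 10.9 in SHR (SD, n = 4 each) and from 22.7 ± 6.97 (SD, n = 4) to 5.63 ± 4.68 (SD, n = 3) in WKY. The 3' to 5' ratio of beta-actin, a sign of RNA quality, moved apart between the strains over the same ages, to 1.18 ± 0.14 in SHR (SD, n = 4) and 1.80 ± 0.23 in WKY (SD, n = 3) at 20 months, a difference that was not tested. The brightest probe sets of Col3a1 and Nppa did not pass (limma adjusted p = 0.0611 and 0.208), while a second Col3a1 probe set did (0.99 ± 0.22, limma adjusted p = 0.0434).

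Limma called 27 interactions from 12 to 20 months, 24 upward and 3 downward, with 714 at an unadjusted p of 0.05. Of the 14 called genes named here, 12 lost their call under at least 1 alternative, while Ltbp2 and Myl4 did not. Ech1, Eln, Pllp and Col1a2 lost theirs under 20, 17, 16 and 15 of 28 alternatives, and Thbs4 under 1. With the day as a random block, which cannot remove a day effect here, Thbs4, Ltbp2 and Myl4 alone of the 14 kept theirs. Calls numbered 4 with the day as a random block, 15, 10 and 9 without SHR 12 months replicate 2, 3 or 4, 14 and 9 without SHR 20 months replicate 1 or 3, 6 without WKY 12 months replicate 1, and 4 and 5 without WKY 20 months replicate 3 or 4. For 16 to 20 months limma called 0 interactions (546 at an unadjusted p of 0.05; 3, 2, 1 and 1 without SHR 16 months replicate 2, SHR 16 months replicate 3, SHR 20 months replicate 3 or WKY 20 months replicate 2). The 3 genes of smallest p, Hbb-b1, Nrn1 and Ltbp2, had interactions of 0.98 ± 0.21, 0.91 ± 0.20 and 0.42 ± 0.09 and did not pass. The inflammation list kept its upward call there (median 0.15, adjusted p = 0.0342 with an estimated correlation), and the matrix, oxidative phosphorylation, sarcomere and fibroblast lists lost theirs (adjusted p = 0.151, 0.151, 0.348 and 0.261 with an estimated correlation).

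**Figure D3:**
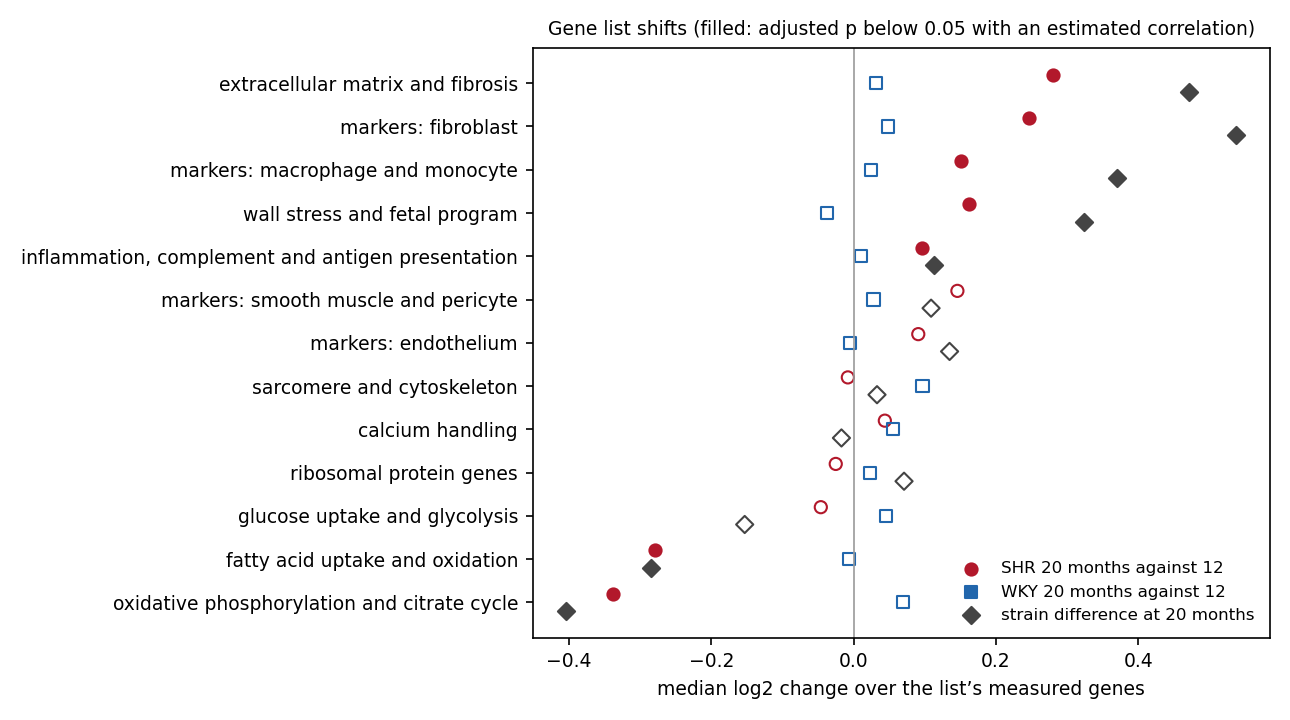
Median log2 change over the measured genes of 13 gene lists (horizontal axis) for SHR at 20 against 12 months (red circles), WKY at 20 against 12 months (blue squares) and SHR against WKY at 20 months (grey diamonds). Filled symbols have an adjusted p below 0.05 with an estimated correlation. The matrix list lies at 0.28 in ageing SHR and 0.03 in ageing WKY, and the oxidative phosphorylation list at -0.34 and 0.07.

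At 20 months the SHR ventricle had higher levels of matrix, stress and immune genes and lower levels of mitochondrial genes than the WKY ventricle. Thbs4 was at 214 ± 25 in SHR (SD, n = 4) and 6.87 ± 0.95 in WKY (SD, n = 3), a log2 difference of 2.66 ± 0.17 (limma adjusted p = 3.35e-11). Col3a1 was higher by 1.64 ± 0.19, Loxl1 by 1.55 ± 0.16, the skeletal actin gene Acta1 by 1.53 ± 0.12, Lyz2 by 1.42 ± 0.25, Emp1 by 1.42 ± 0.09, Akip1 by 1.38 ± 0.14 and the calcification inhibitor gene Mgp by 1.35 ± 0.16 log2. Nppa was at 3982 ± 804 in SHR (SD, n = 4) and 1605 ± 191 in WKY (SD, n = 3), and Nppb was higher by 0.60 ± 0.16 log2. Ech1, Acadvl, Pfkm (muscle phosphofructokinase), Dhrs7c, Bckdha, Gstm7, Amd1 and Arhgap1 were lower, with log2 differences between -1.06 and -1.23. Second probe sets of Pfkm (0.04 ± 0.14) and Arhgap1 (-0.01 ± 0.06) did not pass.

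Of the 50 matrix genes 29 were higher and 1 (Lamb2) lower in SHR at 20 months (median 0.47, adjusted p = 0.015 with an estimated correlation), with Col1a1 at 1.26 ± 0.23, Spp1 at 0.72 ± 0.09, Timp1 at 0.99 ± 0.12, Fn1 at 0.82 ± 0.11 log2, and Postn at 57.2 ± 12 in SHR (SD, n = 4) and 6.97 ± 5.87 in WKY (SD, n = 3). Of 42 oxidative phosphorylation genes 20 were lower and 0 higher (median -0.40, adjusted p = 0.015 with an estimated correlation), with Ndufv2 at -1.02 ± 0.15 and Ndufb5 at -0.82 ± 0.12. A second Ndufb5 probe set did not pass (-0.18 ± 0.16), and of 2 other Fn1 probe sets 1 passed in the same direction (0.48 ± 0.11) and 1 did not (0.14 ± 0.08). Of 39 fatty acid genes 16 were lower and 0 higher (median -0.29, adjusted p = 0.015 with an estimated correlation), with Cpt2 at -0.82 ± 0.11, while Cd36, the fatty acid transporter gene, did not pass at -0.29 ± 0.14. Of the fibroblast markers 8 and of the macrophage markers 7 were higher and 0 lower, C1qb among them at 1.23 ± 0.15, and 12 inflammation genes were higher and 3 (Cd74, Tap1 and Alox15) lower, C1s among them at 0.95 ± 0.12 (adjusted p = 0.015 for all 3 lists with an estimated correlation). Of 14 wall stress genes 6 were higher and 0 lower (median 0.32, adjusted p = 0.0176 with an estimated correlation). Pla2g2a was higher by 0.99 ± 0.11. The brightest Myh6 probe set was lower at -0.86 ± 0.14 and a second passed in the same direction (-0.83 ± 0.25, limma adjusted p = 0.0204), while another, dimmer, had the opposite sign at 0.54 ± 0.22 and did not pass. The glycolysis and atrial lists lost their calls (adjusted p = 0.213 and 0.157 with an estimated correlation).

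At 12 months the strains already differed in many genes, but camera called neither the matrix nor the mitochondrial lists. With fry 10 of the 27 lists passed. The mean log2 value of the matrix genes ran from 6.502 to 6.62 on SHR arrays and from 6.353 to 6.445 on WKY arrays, without overlap. The same means of the fatty acid and oxidative phosphorylation genes overlapped. A matrix difference at 12 months is therefore not excluded. Acta1 was at 2017 ± 163 in SHR and 906 ± 150 in WKY (SD, n = 4 each), a log2 difference of 1.14 ± 0.11 (limma adjusted p = 8.83e-08). Aldh6a1, the caveolin gene Cav1, the monoamine oxidase gene Maoa, Myh1 and Akip1 were higher in SHR by 1.40 ± 0.14, 1.27 ± 0.15, 1.08 ± 0.13, 1.02 ± 0.12 and 0.99 ± 0.13 log2, and the phospholamban gene Pln, a regulator of calcium uptake, by 0.90 ± 0.10. Myl7, Arhgap1, Hba-a3, Txnip, Dnaja3, Ttc3, Amd1, Prkaca and the sodium pump subunit gene Atp1b1 were lower, with log2 differences from -2.05 to -0.73. Thbs4 was higher by 0.97 ± 0.16, the collagen-modifying enzyme gene Plod2 by 0.42 ± 0.07 and C1qb by 0.64 ± 0.14, and Cpt2 and Acadvl were lower by log2 differences of -0.51 ± 0.10 and -0.61 ± 0.13. Col3a1 and Timp1 were higher by 0.55 ± 0.17 and 0.36 ± 0.11, and both lost their calls under some alternatives. A second Col3a1 probe set did not pass (limma adjusted p = 0.128), and of 3 other Akip1 probe sets 2 passed in the same direction and 1 did not. The brightest Nppa probe set did not pass (0.48 ± 0.18, limma adjusted p = 0.0786), while 3 others did.

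The macrophage list was called at 12 months (median 0.18, with Lyz2, C1qb and Cd53 higher among 11) and lost its call with an estimated correlation (adjusted p = 0.18). Nr4a1, an early response gene, was higher by 1.38 ± 0.28. Kctd13 had the largest log2 difference, 3.14 ± 0.77, on a probe set that ran from 214 to 2478 over the SHR arrays of 12 months, while 2 other Kctd13 probe sets did not pass at -0.06 ± 0.10 and -0.14 ± 0.07. Other probe sets of Arhgap1, Txnip and Atp1b1 did not pass and had the opposite sign.

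At 16 months the fatty acid and macrophage lists differed (adjusted p = 0.042 for both with an estimated correlation). The matrix and oxidative phosphorylation lists differed only with the preset correlation (adjusted p = 0.148 and 0.218 with an estimated correlation). Thbs4 was at 118 ± 45 in SHR and 5.25 ± 2.28 in WKY (SD, n = 4 each), a log2 difference of 1.96 ± 0.16 (limma adjusted p = 2.5e-09). Acta1, Akip1, Nppa, Maoa, Bgn, Cav1 and Loxl1 were higher in SHR by 1.17 to 1.53 log2, Col3a1 by 1.06 ± 0.17, C1qb by 1.03 ± 0.14 and Timp1 by 0.79 ± 0.11. Arhgap1, Amd1, Klf9, Pfkm, Hba-a3, Acadvl, Ppp2r3a, Dnaja3, Ech1, Cpt2 and Got2 were lower, with log2 differences from -1.19 to -0.74. A second, dim Arhgap1 probe set was called in the opposite direction (0.24 ± 0.06, limma adjusted p = 0.00421). Second probe sets of Pfkm and Got2 (0.12 ± 0.13 and 0.17 ± 0.13) and of Klf9 and Ppp2r3a (-0.42 ± 0.16 and -0.26 ± 0.14) did not pass. The brightest Myh6 probe set was lower at -0.43 ± 0.13, which lost its call under some alternatives, while of 2 others 1 was lower (-0.92 ± 0.23, limma adjusted p = 0.0056) and 1, dimmer, was higher at 0.58 ± 0.20.

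Of the matrix list 21 genes were higher and 1 (Lamb2) lower at 16 months (median 0.24, adjusted p = 0.148 with an estimated correlation). Of the fatty acid list 16 were lower and 2 (Pdk4 and Hadh) higher (median -0.18, adjusted p = 0.042 with an estimated correlation). Of the oxidative phosphorylation list 12 were lower and 1 (Cox5a) higher (median -0.15, adjusted p = 0.218 with an estimated correlation). Of the macrophage markers 6 were higher and 0 lower (median 0.17, adjusted p = 0.042 with an estimated correlation). The fibroblast, wall stress, atrial and glycolysis lists lost their calls (adjusted p = 0.148, 0.0902, 0.148 and 0.204 with an estimated correlation).

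Limma called 824 probe sets between the strains at 12 months (491 higher and 333 lower in SHR), 1408 at 16 months (833 and 575) and 1263 at 20 months (764 and 499). Averaged over the ages it called 2654 (1652 and 1002), led by Kctd13 at 2.97 ± 0.45, Thbs4 at 1.86 ± 0.09 and Acta1 at 1.40 ± 0.07 among the higher and Arhgap1 at -1.26 ± 0.10, Amd1 at -1.02 ± 0.05 and Hba-a3 at -0.97 ± 0.06 among the lower. Cd36, with intensities near the added 32, did not pass at -0.08 ± 0.08. The other 2 Kctd13 probe sets did not pass (-0.06 ± 0.06 and 0.001 ± 0.042), and another Arhgap1 probe set was called in the opposite direction (0.10 ± 0.03, limma adjusted p = 0.0283). The same 249 probe sets were called higher and the same 184 lower at all 3 ages, where 5.9 and 1.8 were expected from independent lists, and 2, Calr and Tsc22d1, were called in opposite directions at different ages. The lists were not independent, because the strains were hybridized in different runs at all 3 ages, so the overlap cannot separate strain from run. Of the 7 lists called in the averaged comparison, the macrophage list alone kept its call (adjusted p = 0.0328 with an estimated correlation). The wall stress, matrix, fatty acid, glycolysis, oxidative phosphorylation and fibroblast lists did not (adjusted p = 0.152, 0.136, 0.0764, 0.212, 0.148 and 0.118 with an estimated correlation). The groups did not overlap for 16.6%, 21.7% and 25% of tested probe sets at 12, 16 and 20 months, where chance gives 2.86%, 2.86% and 5.71%.

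The direction split depended on the scaling. Higher calls made up 59.6%, 59.2%, 60.5% and 62.2% of those at 12, 16 and 20 months and averaged, and 35.9%, 35.6%, 38.8% and 34.9% after median centring, with values between 46.4% and 53.7% after quantile or cyclic loess normalization. With the day as a random block 577, 1085, 998 and 2141 were called, and because no day held both strains these counts cannot separate strain from run.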

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

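The tests of the run, lot and cocktail, of a constant offset, of the cell shares and of the atrial markers were chosen after the results were seen; the splits of the arrays and the run day test were set before.

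The strain difference, with 2654 called probe sets averaged over the ages, was weighed against the hybridization run, chip lot and cocktail, which differ between the strains throughout. Spiked bacterial control transcripts, a signal outside the gene comparisons, were brighter on the SHR arrays by a median of 0.696 log2 over 9 probe sets. Each array had been scaled to a common trimmed mean, so the controls are measured relative to the rat signal. Their difference therefore cannot separate the run from the amount of labelled rat RNA. Strain and run cannot be told apart for any gene that differs alike at all ages, because no day, recorded lot or cocktail held both strains. An offset between the runs that is constant on the log2 scale used cancels in the interaction by construction, without a test. Such an offset therefore does not give the wider matrix difference at 20 than at 12 months (median 0.326 log2, the interaction restated). The difference at each age stays open to it. A constant factor between the runs need not cancel for dim genes, because a fixed amount was added to the intensities before log2. Whether such a factor gave part of the wider matrix difference was not tested. Strain itself, a constant factor between the runs, a run effect that changed from day to day and RNA quality, which was not tested, stay open.

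The matrix rise and the mitochondrial fall in SHR from 12 to 20 months were weighed against the hybridization day and against a smaller share of cardiomyocytes. The largest difference between days within an age was 0.096 in the matrix score and -0.098 in the oxidative phosphorylation score, against 0.414 and -0.324 from 12 to 20 months, but all 20 months arrays shared a day of their own, so day and age cannot be told apart there. For the matrix rise, a smaller cardiomyocyte share in which all other cells rise alike is argued against as the whole cause. The matrix score rose over the mean of the endothelial and smooth muscle scores by 0.315 (0.651 ± 0.032 against 0.336 ± 0.043, SD, n = 4 each; exact permutation p = 0.0286, the smallest that 70 splits allow). A share lowered by fibroblasts alone need not raise those markers, so this contrast cannot decide on it. For the mitochondrial fall, a smaller cardiomyocyte share as the whole cause is argued against only if sarcomere expression per cell did not rise. The sarcomere score rose over the oxidative phosphorylation score by 0.371 (0.533 ± 0.131 against 0.161 ± 0.041, SD, n = 4 each, exact permutation p = 0.0286). Most of that is the fall of the oxidative phosphorylation score itself (-0.324). Both contrasts were chosen after the lists had been tested on the same arrays, so they restate the list results and their p-values add no separate evidence. Age and hypertension in SHR, a rise of fibroblasts alone and the day stay open.

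Myl7 was high on the 4 WKY arrays of 12 months, where Myl4 was also higher than on the other WKY arrays, which was weighed against atrial tissue in those samples. The other atrial markers differed between these and the other WKY arrays by 0.039 log2 (7.63 ± 0.07, SD, n = 4, against 7.592 ± 0.087, SD, n = 7; exact permutation p = 0.464). Their high level in ventricle would hide a small atrial share, so atrial tissue and a change of Myl7 in the ventricle cannot be told apart. A second Myl7 probe set did not pass between 12 and 16 months at -0.91 ± 0.17 log2 (limma adjusted p = 0.0503). Age stays among the open explanations, untested.

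Differences between the strains in the change from 12 to 20 months, found by the interaction test, were 2.528 for Myl7, 1.687 for Thbs4, 1.217 for Tsc22d1, 1.169 for Eln, 1.102 for Loxl1, 1.035 for Col1a2, 1.002 for Myl4, 0.889 for Capg, 0.867 for Postn, 0.781 for Fn1, 0.708 for Ltbp2, -0.69 for Pllp, -0.762 for Ech1 and -1.066 for Rpl3l, in log2. Of these genes Thbs4, Ltbp2 and Myl4 alone kept their calls with the day as a random block. The 20 months arrays of each strain filled a day of their own, so that block cannot remove a day effect from this interaction.

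Arrays far from the other 3 of their group (Dixon's test) were found in 15 of 410 pairs of gene and group, 3.7%, where chance gives about 1 in 20. In SHR these were Arhgap1 at 27.7 (others 10.6 to 12.8) and Nppb at 650.3 (932 to 995.8) on 12 months replicate 1, Pla2g2a at 121.7 (144.3 to 148.6) on 12 months replicate 4, Eln at 19.9 (47.7 to 51.1), Nr4a1 at 220.9 (56.4 to 73.3) and Cav1 at 99.1 (52.2 to 57.9) on 16 months replicates 1, 3 and 4, Amd1 at 14.4 (21.8 to 22.7) on 20 months replicate 1, and Acot2 at 56.3 (103.6 to 115.7) and Lyz2 at 752.7 (361 to 405.1) on 20 months replicate 4. In WKY they were Nppa at 1509.8 (1842.3 to 1881.7) and Pla2g2a at 98 (83.3 to 84.7) on 12 months replicate 2, and Pllp at 63.3 (47.7 to 49.6), Atp1b1 at 880.3 (987 to 1007.3), Cnrip1 at 23.2 (14.2 to 14.9) and Vtn at 46.5 (37.4 to 38.3) on 16 months replicates 2, 3, 4 and 4.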

How the results depend on the processing

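Leaving out the SHR arrays of 16 months by day and the fluidics module block were chosen after the data were seen, as were, for lists, the loess, median and day settings. Of the counts recomputed, 224 lay within 1.5 times the value reported and 63 did not; of values of named genes, 3502 kept their side of the threshold, 305 lost the call, 26 gained it and 5 turned; of list calls, 425 were kept, 84 lost and 0 turned. The cause was not tested except where fewer arrays or probe sets entered. Signal over background limits dim genes.

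SHR at 16 against 12 months (27 calls) gave 52 with array weights, 50 without a trend, 67 with the filter at the 60th percentile, 1 with only the arrays compared, 42 with the run day as a fixed block, 0 within run day 2 alone and 136 without the SHR 16 months arrays of run day 3. SHR at 20 against 16 months (6) gave 10 with the filter at the 60th percentile, 3 with no filter, 0 with only the arrays compared, 0 with a pseudocount of 1, 10 with a pseudocount of 100, 3 with the run day as a random block, and 11 and 60 without the SHR 16 months arrays of run day 2 or 3. SHR at 20 against 12 months (337) gave 214 with the run day as a random block. WKY at 16 against 12 months (1) gave 3 with array weights and 2 with median centring, cyclic loess, the filter at the 60th percentile or the run day as a random block. WKY at 20 against 16 months (0) gave 5 with array weights, 1 with no filter, and 2 with a pseudocount of 1 or quantile normalization. WKY at 20 against 12 months (4) gave 0 with only the arrays compared or the run day as a random block and 1 with the replicate or the fluidics module as a block. The interaction from 12 to 20 months (27) gave 71 with array weights, 54 with the filter at the 60th percentile, 16 with no filter, 10 with the fluidics module as a block, 7 with a pseudocount of 1 and 4 with the run day as a random block. The interaction from 16 to 20 months (0) gave 2 and 28, and the strain difference at 16 months (1408) gave 849 for the first, without the SHR 16 months arrays of run day 2 or 3. Atp2a2 in SHR at 20 against 12 months, not called at -0.13 log2, was 0.047 with cyclic loess and -0.205 to 0.001 with an array left out. Col3a1 in WKY at 20 against 12 months, not called at 0.05, was -0.051 with array weights and -0.14 to 0.222 with an array left out.

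Leaving out each array in turn gave 562 to 690 calls for the strain difference at 12 months, 1080 to 1404 at 16 months, 906 to 1169 at 20 months and 2410 to 2638 averaged, 4 to 69, 3 to 13 and 160 to 350 for SHR at 16 against 12, 20 against 16 and 20 against 12 months, 1 to 2, 0 to 0 and 0 to 6 for the same in WKY, and 4 to 35 and 0 to 3 for the interactions from 12 and from 16 to 20 months. Of 71 list calls, 33 were kept with an estimated correlation.

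Residuals of arrays with the same replicate number correlated at -0.34 to 0.21 (mean -0.01, and 0.01 for other pairs), and 3 of 23 arrays correlated best with their own number, so the numbers were not taken as pairs. As a block they gave 793, 1342, 1198 and 2574 calls for the strain differences, 24, 5 and 305 in SHR, 1, 0 and 1 in WKY, and 21 and 0 for the interactions. The station and the chip lot were not run as blocks, since the second station held 1 group and each lot 1 strain, and the averaged difference has no value with only the arrays compared, which are all arrays.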

Other observations

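All tests in this part were set before the results were seen. Other splits of the same arrays into groups of the same sizes were counted, the real split included. Chance can be excluded for the strain difference at 12 months (1 of 35 splits gave as many calls as the real 824, highest other 8), at 16 months (1 of 35, real 1408, highest other 3), at 20 months (1 of 35, real 1263, highest other 539) and averaged (1 of 100 splits drawn, real 2654, highest other 1127). The largest other splits at 20 months kept the 3 WKY arrays with 1 SHR array, and so nearly repeated the real split. Chance can also be excluded for SHR at 20 against 12 months (1 of 35, real 337, highest other 2). For SHR at 16 against 12 months 1 of 35 splits gave as many calls (real 27, highest other 7, given by the split that follows day 2). Those 27 calls became 1 with only the arrays compared and 4 without SHR 12 months replicate 2, so chance is not excluded there. For WKY at 20 against 12 months 1 of 35 splits gave as many calls (real 4, highest other 1), the smallest share possible. Those 4 calls were lost with the day as a random block and with only the arrays compared. They were also lost without WKY 12 months replicate 1 or WKY 20 months replicate 2, so chance is not excluded there. For the interaction from 12 to 20 months 4 of 100 splits drawn gave as many calls (real 27, highest other 46). The 3 other splits all kept the SHR arrays of each age together and regrouped only the WKY arrays. The splits regrouped both strains, so the SHR age change alone can set the real split apart. They cannot exclude chance for the interaction. With the day as a random block 4 interactions were called, and without WKY 12 months replicate 1 or WKY 20 months replicate 3 or 4 there were 6, 4 and 5.

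Chance cannot be excluded for SHR at 20 against 16 months (3 of 35 splits gave as many as the real 6, highest other 33), WKY at 16 against 12 months (4 of 35, real 1, highest other 2), WKY at 20 against 16 months (35 of 35, real 0, highest other 3) and the interaction from 16 to 20 months (100 of 100, real 0, highest other 1). The split with 33 calls joined the day 3 arrays of SHR at 16 months with replicates 1 and 2 of SHR at 20 months. The mean intensity ran from 80.5 to 89.4 on these arrays and from 92.2 to 98.7 on the others of the 2 groups. Whether this difference in signal gave the 33 calls was not tested. With the day as a random block 3 probe sets were called between SHR at 20 and 16 months.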
